A study of Mus musculus with 88 samples.

How the data were processed

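RNA was measured in 88 libraries from 44 groups of 2 replicates. Per the labels, the groups were mouse ES, TS, PrES and XEN cells kept alone for 0, 1 or 3 days, or cultured for 1 or 3 days with 1 or 2 of the other cell types. ES and TS cells gave 26 libraries each, and PrES and XEN cells gave 18 each. "ES with TS" means libraries labelled as ES cells taken from a culture with TS cells. The labels do not state how cocultured cell types were separated before RNA was made. They also do not say whether replicates were separate cultures, so the p-values of genes measure the spread between these samples, which may be technical.

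The deposited table holds estimated counts per gene symbol from kallisto 0.46.2, written as whole numbers. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20.0.422, trimmed with Trim Galore 0.6.4 and assigned on mm10. The notes state neither the transcript annotation nor how transcripts were summed to genes, and the strandedness is not stated. Of 36040 symbols, 32515 (90.2%) were found in the RefSeq gene table for GRCm38.p6. Symbols of near-identical paralogs (Pramel, Zscan4, Prl2c, Serpinb9 and placental cathepsin genes, histone genes, Hmga1-rs1) share sequence, so their separate values are uncertain.

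Library totals ran from 3972357 to 22857042, with a median of 6704568. The sample descriptions carry 3 codes, taken here as sequencing runs although the labels do not explain them. The first holds 41 libraries, all numbered replicate 1, and the second 42 libraries, all numbered replicate 2. The third holds 5 deeper libraries (19163651 to 22857042, against 3972357 to 13439185 elsewhere), namely PrES alone at days 0 and 1 in both replicates and replicate 1 of TS with XEN at day 1. Comparisons of PrES cells alone at day 0 or day 1 with any other group therefore also compare runs. A gene at 1 CPM in the shallowest library has about 4 counts, so low genes carry large counting error.

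Tests were made in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) by quasi-likelihood F tests, with TMM factors, filterByExpr by group (minimum count 10, minimum total 15) and 1 coefficient per group. One model was fitted per cell type on all of its libraries (15219 genes for ES, 14568 for TS, 14626 for PrES, 14399 for XEN). A further model on the 24 monoculture libraries (16889 genes) served the comparison of PrES with XEN cells. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and "rose", "fell" and "changed" are used only for called genes. A list is "higher" or "lower" by the direction of its test. Values are log2 changes ± standard error (the log2 change over the square root of F) and mean CPM ± SD of 2 libraries after TMM scaling within the model.

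The comparisons, written before the data were examined, were each day 3 coculture against the same cells alone at day 3, all day 1 cocultures of a cell type against the same cells alone in 1 joint test, and PrES against XEN as the partner. Others were the non-additivity of 3-way cultures (the 3-way change minus the sum of both 2-way changes), day 3 minus day 0 alone, and PrES minus XEN alone. Gene lists, settings and the rule for named genes were fixed at the same point. That rule took, at adjusted p under 0.05, at least 20 CPM in the higher group and no overlap between libraries, the 4 largest rises and falls per coculture by log2 change. Rises were ranked after genes at least 4-fold higher in a partner were set aside, and the 2 largest of those were named apart. It took 8 rises and 8 falls per monoculture comparison, 4 and 4 for the partner comparison, and the 3 smallest p for joint and non-additivity tests. It also took up to 4 members with the smallest adjusted p of each list past its test or with at least 3 called members, and 10 lineage markers (Pou5f1, Sox2, Nanog, Cdx2, Eomes, Elf5, Gata4, Gata6, Sox17, Pdgfra). The text names a subset of these.

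There were 26 lists with 362 members in the table. They covered core and naive pluripotency, formative and primed epiblast, primitive streak, neural ectoderm, trophoblast stem cells, differentiated trophoblast, primitive, parietal, visceral and anterior visceral endoderm, and embryonic fibroblasts (feeders). The rest covered FGF-ERK, WNT, BMP, NODAL and p53 targets, cholesterol synthesis, hypoxia and glycolysis, cell cycle, amino acid and unfolded protein stress, immediate early genes, the interferon response, imprinted genes, germline genes, and X inactivation with Y-linked genes. Lists were tested with camera (inter-gene correlation preset at 0.01), adjusted over all lists and all 16 coculture or 6 monoculture comparisons. A p from a correlation estimated per list is added where it did not pass.

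Genes with no count in a group are given as "at least" folds against a floor of 3 counts over the 2 libraries. Genes with 1 to 3 counts are given as a ratio with a binomial counting interval, and both cover counting error only. The share of a partner's transcripts in a coculture library was estimated from genes at least 32-fold higher in that partner than in the recipient, and at 50 CPM or more, when each was alone. It is the summed excess over the recipient alone as a percentage of the partner's own level.

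Alternatives planned beforehand were RLE size factors, no low-count filter, DESeq2 1.42.0, the replicate number as a block, a model on the compared groups alone, leaving out each library in turn, leaving out genes at least 4-fold higher in a partner, the block without the third run code, and for lists an estimated correlation and fry. One alternative was added after the data were seen, in which each partner's share, here against its level in the same coculture, times its profile there was subtracted from each library. Thresholds of 16-fold and 64-fold for partner genes, and fixed shares for formative genes in PrES with ES and endoderm genes in ES with XEN, were added then too. Simulated data had the real depths and 200 changed genes per comparison. There edgeR recovered 28 to 55% of 2-fold and 62 to 82% of 4-fold changes. Unchanged genes made up 1 of 116 to 15 of 152 calls (XEN with ES). Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.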

Results

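The 44 groups held 2 libraries each, of 3972357 to 22857042 estimated counts. Every comparison was 2 libraries against 2, except where a test joined several groups.

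ES cells alone lost naive pluripotency transcripts over 3 days. Zfp42 (Rex1), a marker of naive ES cells, fell 7.78-fold (log2 -2.96 ± 0.11, 149.5 ± 8.48 against 1162 ± 24.6 CPM, adjusted p = 1.55e-16). Nanog, a core pluripotency factor, fell 4.56-fold (202 ± 4.03 against 924 ± 54 CPM, adjusted p = 1.73e-16). The naive list was lower (0 of 14 rose and 13 fell, median log2 -2.98, adjusted p = 1.23e-31). Fgf5, a marker of the formative epiblast, rose 413-fold (log2 8.69 ± 0.29, 234 ± 4.25 against 0.555 ± 0.172 CPM), beside Otx2 at 62.0 against 4.73 CPM and the DNA methyltransferase Dnmt3b at 302 against 54.2 CPM in the formative list (12 of 14 rose and 1 fell, median log2 2.50, adjusted p = 9.76e-18). Pou5f1, which both states express, was at 322 against 398 CPM (adjusted p = 0.108), and was called lower without the low-count filter (0.00895) and without replicate 1 of day 0 (0.00312). Targets of p53 were higher as a list (10 of 12 rose and 1 fell, median log2 1.54, adjusted p = 5.97e-10). It included the cell cycle inhibitor Ccng1 at 739 against 197 CPM and the apoptosis gene Pmaip1 at 556 against 44.0 CPM. Higher too were imprinted genes (15 of 19 rose and 1 fell, median log2 1.84, adjusted p = 5.22e-11), NODAL targets (5 of 8 rose and 0 fell, median log2 1.27, adjusted p = 4.37e-06) and glycolytic genes such as Slc2a1, the glucose transporter (10 of 16 rose and 2 fell, 12 and 2 adjusted over the list alone, median log2 0.80, adjusted p = 0.000748). The anterior visceral endoderm list had a median and a mean of opposite sign (2 of 6 rose and 2 fell, median log2 -0.08, mean log2 0.51, tested direction up, adjusted p = 0.0497, 0.123 with an estimated correlation). The edgeR test called 5874 of 15219 genes, 2978 higher and 2896 lower.

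TS cells alone lost Eomes and gained placental genes. Eomes, a T-box factor of TS cell self-renewal, fell 70.5-fold (log2 -6.14 ± 0.27, 2.49 ± 1.53 against 174 ± 2.46 CPM, adjusted p = 8.2e-14), and Elf5, a trophoblast stem cell factor, fell 6.45-fold (38.4 ± 3.4 against 248 ± 6.4 CPM). Cdx2 went from 15.4 CPM to no count (at least 63.1-fold lower). The stem cell list had log2 above 0 in 6 of 15 members (median -1.34). Targets of FGF-ERK signalling, which sustains TS cells, were lower (1 of 13 rose and 11 fell, 1 and 12 adjusted over the list alone, median log2 -4.80, adjusted p = 8.18e-16), including the ERK phosphatase Dusp6 (1.17 ± 0.761 against 369 ± 23.6 CPM). Cell cycle genes were lower too (0 of 19 rose and 18 fell, median log2 -1.63, adjusted p = 9.59e-19). Plk1, a mitotic kinase, was at 36.4 against 208 CPM. Differentiated trophoblast genes were higher (15 of 17 rose and 0 fell, 16 and 0 adjusted over the list alone, median log2 5.37, 4.77 with members at 0 set to their bound, adjusted p = 5.97e-10), among them the placental gene Plac1 (1099 ± 121 against 0.614 ± 0.682 CPM) and the kinase Nrk (860.3 against 1.53 CPM). Interferon genes were higher (9 of 10 rose and 0 fell, median log2 3.73, adjusted p = 0.000766, 0.054 with an estimated correlation). In it, Stat1, the transducer of that response, was at 54.5 against 5.22 CPM. The WNT target list had 1 called members higher and 4 lower (adjusted p = 0.197). In all, 7555 of 14568 genes changed (3876 higher, 3679 lower).

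PrES alone had higher parietal endoderm genes at day 3 than day 0. Sparc, a matrix protein of parietal endoderm, rose 2.25-fold (log2 1.17 ± 0.08, 10640 ± 488 against 4726 ± 109 CPM, adjusted p = 9.88e-09), beside the collagen Col4a2 (802 ± 90.4 against 299 ± 31.9 CPM) and Snai1, a factor of the epithelial to mesenchymal transition (70.8 against 9.45 CPM). The parietal endoderm list was higher (11 of 13 rose and 1 fell, median log2 1.11, adjusted p = 7.13e-12), and the primitive endoderm list was mixed (12 of 19 rose and 4 fell, 13 and 5 adjusted over the list alone, median log2 0.50, adjusted p = 0.00157, 0.196 with an estimated correlation). Dppa2, a pluripotency-associated gene, fell (78.0 against 233 CPM), and Pou5f1 was at 50.9 against 37.4 CPM (adjusted p = 0.0901, 0.0345 without replicate 1 of day 0). Germline genes were lower as a list (0 of 10 rose and 5 fell, 1 and 7 adjusted over the list alone, median log2 -1.13, adjusted p = 0.0098, 0.13 with an estimated correlation). The test called 4787 of 14626 genes (2399 higher, 2388 lower). Day 0 and day 3 libraries came from different runs, so run and time cannot be separated here. One histone symbol, Hist1h2ap, had no count in either day 0 library and 155 CPM at day 3 (at least 2100-fold). Without the low-count filter, 1731 genes were called higher and 3039 lower, a split 13.8 points further towards falls, with a median log2 change of -0.1 over all genes.

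XEN cells alone gained visceral endoderm genes. Ttr, the transthyretin carrier, rose 25.8-fold (log2 4.69 ± 0.13, 611 ± 103 against 23.6 ± 1.29 CPM, adjusted p = 4.54e-16), and Rbp4, the retinol carrier, rose 10.1-fold (665 ± 30.1 against 65.7 ± 3.24 CPM) in a higher list (9 of 12 rose and 1 fell, median log2 2.97, adjusted p = 4.04e-07). Primitive endoderm genes were higher (12 of 19 rose and 1 fell, 14 and 1 adjusted over the list alone, median log2 0.41, adjusted p = 1.65e-05), including the endocytic adaptor Dab2 (1926 against 824 CPM). Id3, a BMP target that blocks differentiation, fell (14.9 against 150 CPM), as did the chromatin protein Hmga1 (1.63 against 77.5 CPM) and the lactate dehydrogenase Ldha (438 against 1687 CPM). Core pluripotency genes (0 of 12 rose and 4 fell, median log2 -0.50, adjusted p = 0.0452, 0.123 with an estimated correlation) and neural ectoderm genes (1 of 4 rose and 2 fell, median log2 -1.28, adjusted p = 0.0208, 0.114 with an estimated correlation) were lower as lists. Gata6 was at 142 against 129 CPM (adjusted p = 0.523). Of 14399 genes, 2685 rose and 2496 fell.

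PrES cells differed from XEN cells in the pluripotency and parietal endoderm lists. At day 3, Pou5f1 was at 52.5 against 0.0747 CPM (PrES against XEN), a ratio of 787 with a counting interval of 141 to 31100. Dppa5a, an RNA-binding protein of ES cells, stood at 1339 against 0.121 CPM (a ratio of 9970 with a counting interval of 2760 to 82300) and Dnmt3l, the methyltransferase cofactor, at 174 against 0.345 CPM. The secreted phosphoprotein gene Spp1 was at 442 CPM with no count in XEN cells (at least 2200-fold). Core and naive pluripotency lists were higher in PrES cells (core, 7 of 14 higher and 0 lower, median log2 1.80, 1.22 with members at 0 set to their bound, adjusted p = 1.18e-12; naive, 7 of 14 higher and 0 lower, 8 and 0 adjusted over the list alone, median log2 1.32, adjusted p = 6.15e-15). Germline genes (8 of 12 higher and 0 lower, 9 and 0 adjusted over the list alone, median log2 2.99, 2.66 with members at 0 set to their bound, adjusted p = 1.06e-05), anterior visceral endoderm genes (6 of 8 higher and 0 lower, median log2 3.42, 2.96 with members at 0 set to their bound, adjusted p = 0.000232), cholesterol synthesis (12 of 19 higher and 0 lower, median log2 0.64, adjusted p = 7.67e-05) and amino acid stress genes (9 of 13 higher and 0 lower, 11 and 0 adjusted over the list alone, median log2 1.45, adjusted p = 5.63e-08) were higher as well. The endocytic receptor genes Cubn (933 ± 37.9 against 25.5 ± 4.33 CPM) and Lrp2 (1429 ± 0.99 against 63.9 ± 8.37 CPM) were higher in PrES cells, and Rbp4 (5.44 ± 2.04 against 613 ± 22.3 CPM) and the proteoglycan Nepn (1.23 against 388 CPM) in XEN cells. Parietal endoderm genes were lower in PrES cells (0 of 13 higher and 8 lower, median log2 -0.72, adjusted p = 4.89e-08), such as Vim, an intermediate filament (21.9 against 181 CPM). Gata6, shared by both, was at 150.3 against 131 CPM (adjusted p = 0.441), and Gata4, its partner factor, at 164 against 295 CPM (adjusted p = 0.000394). The test gave 5193 of 16889 genes (2847 higher in PrES, 2346 lower).

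At day 0, where the PrES libraries came from the run of 5 deeper libraries, 8441 genes differed (4866 higher, 3575 lower). The median log2 difference over all genes was 0.104, and DESeq2 size factors moved it by -0.104 to 0. Dppa5a was at 2207 CPM in PrES cells against 0.0560 in XEN cells (a ratio of 35800 with a counting interval of 6420 to 1410000), and Zfp42 at 139 against 0.582 CPM. The naive list had 11 of 14 members higher (adjusted p = 3.18e-12), and the list of fibroblast markers had 11 higher and 3 lower (adjusted p = 0.269).

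With TS cells, naive transcripts of ES cells were higher at day 3. Zfp42 rose 4.29-fold against ES cells alone (log2 2.10 ± 0.11, 640.1 ± 62.4 against 149.5 ± 8.48 CPM, adjusted p = 3.65e-12), and Nr0b1 (Dax1), an orphan receptor of the naive network, rose 5.58-fold (170.1 ± 15.1 against 30.5 ± 6.61 CPM). Nanog rose 2.04-fold (412 ± 8.65 against 202 ± 4.03 CPM) and Sox2, the core factor, 2.99-fold (63.5 ± 16.1 against 21.4 ± 3.48 CPM). All 14 members of the naive list rose (adjusted p = 2.62e-59). Formative genes were lower (0 of 14 rose and 6 fell, 1 and 7 adjusted over the list alone, median log2 -0.54, adjusted p = 6.57e-05). In it, Fgf5 was at 92.2 ± 16 against 234 ± 4.25 CPM. Targets of p53 were lower (0 of 12 rose and 6 fell, 0 and 8 adjusted over the list alone, median log2 -0.78, adjusted p = 1.33e-08), including the p53 inhibitor Mdm2 (159.7 against 244 CPM) and Pmaip1 (288 against 556 CPM). Lefty2, a NODAL inhibitor and target, rose 5.9-fold (332 ± 6.85 against 56.5 ± 1.67 CPM), while the NODAL target list, Lefty2 included, was mixed (2 of 8 rose and 2 fell, median log2 -0.13, mean log2 0.19, tested direction up, adjusted p = 0.811). Park2, a ubiquitin ligase gene, rose (325 against 9.15 CPM). Core pluripotency genes went both ways (5 of 14 rose and 2 fell, median log2 0.08, adjusted p = 0.0169, 0.265 with an estimated correlation), and cholesterol genes were lower (0 of 19 rose and 5 fell, median log2 -0.20, adjusted p = 0.0155, 0.282 with an estimated correlation). Of 15219 genes, 1102 rose and 839 fell (1941 in all), and 113 of the rises were genes at least 4-fold higher in TS cells. The TS share of the libraries was -0.2 ± 0.01%. Counts were 939 and 1230 without replicates 1 and 2 of ES alone, 898 without replicate 2 of ES with TS.

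With PrES cells, ES cells showed higher formative and lower NODAL and p53 transcripts. Otx2, a homeobox factor of the formative epiblast, rose 2.22-fold (log2 1.15 ± 0.11, 137 ± 5.95 against 62.0 ± 0.0923 CPM, adjusted p = 4.21e-07), beside Dnmt3b (547 ± 115 against 302 ± 8.37 CPM) in a higher list (4 of 14 rose and 0 fell, 5 and 0 adjusted over the list alone, median log2 0.41, adjusted p = 4.01e-07). Tdgf1 (Cripto), the NODAL co-receptor, fell 2.06-fold (728 ± 24.8 against 1500 ± 38.8 CPM). Members of the NODAL target list were lower (0 of 8 rose and 3 fell, 0 and 4 adjusted over the list alone, median log2 -0.54, adjusted p = 1.32e-08), such as Pitx2, a homeobox target (23.7 against 79.3 CPM). Id1, a BMP target, fell 3.1-fold (29.8 ± 6.15 against 92 ± 14.6 CPM) in a list with 0 called members higher and 2 lower (adjusted p = 4.56e-05). Targets of p53 were lower (0 of 12 rose and 7 fell, 0 and 8 adjusted over the list alone, median log2 -0.56, adjusted p = 1.63e-11), as were genes of amino acid stress (0 of 13 rose and 5 fell, 0 and 7 adjusted over the list alone, median log2 -0.45, adjusted p = 8.74e-07) such as the asparagine synthetase Asns (215 against 352 CPM). Nanog fell (144 against 202 CPM, adjusted p = 0.000342), and Sox2 was at 31.2 against 21.4 CPM (adjusted p = 0.0963, 0.0373 without the low-count filter and 0.0425 without replicate 1 of ES with PrES). The test called 333 genes higher and 468 lower (801 of 15219), and 526 and 484 without the low-count filter. Partner genes made up 27 of the rises, and the PrES share was 0.13 ± 0.08%. The count was 302 and 434 without replicates 1 and 2 of ES alone, 398 without replicate 2 of ES with PrES.

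With XEN cells, NODAL pathway and naive transcripts of ES cells were far lower. Tdgf1 fell 27.9-fold (log2 -4.80 ± 0.08, 53.9 ± 0.858 against 1500 ± 38.8 CPM, adjusted p = 8.09e-24), Lefty1, a secreted NODAL inhibitor, fell 18.8-fold (5.18 ± 5.11 against 97.4 ± 3.29 CPM), and the NODAL list was lower (0 of 8 rose and 7 fell, 0 and 8 adjusted over the list alone, median log2 -3.61, adjusted p = 8.95e-66). Nanog fell 8.34-fold (24.2 ± 1.67 against 202 ± 4.03 CPM) and Dppa5a 7.21-fold (232 ± 21.4 against 1674 ± 88.9 CPM) in the naive list (1 of 14 rose and 10 fell, 1 and 11 adjusted over the list alone, median log2 -1.92, adjusted p = 5.15e-34). The mesoderm gene T (brachyury) had no count, from 15.1 CPM alone (at least 70.9-fold lower), and primitive streak genes were lower as a list (0 of 7 rose and 4 fell, 0 and 6 adjusted over the list alone, median log2 -3.89, adjusted p = 9.73e-11). Formative genes were higher (4 of 14 rose and 1 fell, median log2 0.61, adjusted p = 0.000361). In it, Otx2 was at 145 ± 10.7 against 62.0 ± 0.0923 CPM. Id1 rose 3.07-fold (282 ± 13.7 against 92 ± 14.6 CPM), opposite to its change with PrES cells, in a BMP list with 3 called members higher and 1 lower (adjusted p = 0.000518). Germline genes were lower (0 of 12 rose and 6 fell, 0 and 7 adjusted over the list alone, median log2 -1.22, adjusted p = 0.000206). That list held the RNA helicase Ddx4 at 10.4 against 25.3 CPM. Hypoxia genes were higher (8 of 16 rose and 0 fell, 9 and 0 adjusted over the list alone, median log2 0.49, adjusted p = 1.73e-08). It included the mitophagy gene Bnip3 at 118 against 54.8 CPM. Endoderm genes were also higher, among them the laminin Lama1 (133 against 3.13 CPM), Sparc (920.5 against 164 CPM) and Gata4 (16.1 against 0.589 CPM). After XEN RNA was subtracted, log2 was -7.28 for Lama1 (adjusted p 0.053), -4.92 for Gata4 (0.238) and -12.98 for Sparc (5.98e-05). The subtracted 7.59 and 8.88% exceed the endoderm genes' median (5.65%, below), so reversals are not read as falls. The primitive endoderm list (14 of 19 rose and 0 fell, 17 and 0 adjusted over the list alone, median log2 3.61, adjusted p = 3.84e-31, 9.35e-07 in the other direction after partner RNA was subtracted) and the parietal endoderm list (9 of 13 rose and 0 fell, 10 and 1 adjusted over the list alone, median log2 2.46, adjusted p = 1.11e-19, 5.57e-14 in the other direction after partner RNA was subtracted) were higher, beside a XEN share of 7.56 ± 0.63%. The aspartic protease gene Pga5, at 7008 CPM in XEN cells alone, reached 924 CPM from 0.200 CPM (a ratio of 4670 with a counting interval of 1600 to 22600). Of 15219 genes, 755 rose and 1069 fell, and 354 of the rises were partner genes. Without partner genes the split was 380 higher and 1024 lower. The count of 1824 was 986 and 1122 without replicates 1 and 2 of ES alone, 1136 and 1076 without replicates 1 and 2 of ES with XEN.

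In the 3-way culture with TS and PrES cells, naive transcripts of ES cells were higher. Zfp42 rose 4.63-fold (log2 2.21 ± 0.11, 693 ± 32.2 against 149.5 ± 8.48 CPM, adjusted p = 6.9e-13), Dppa3, a maternal chromatin factor, rose 4.96-fold (92.8 ± 4.56 against 18.7 ± 1.19 CPM), and the naive list was higher (13 of 14 rose and 0 fell, 14 and 0 adjusted over the list alone, median log2 2.26, adjusted p = 4.45e-49). Fgf5 fell (79.7 ± 6.17 against 234 ± 4.25 CPM) in a lower formative list (1 of 14 rose and 7 fell, median log2 -0.72, adjusted p = 2.19e-06). P53 targets were lower (0 of 12 rose and 4 fell, 0 and 6 adjusted over the list alone, median log2 -0.48, adjusted p = 5e-06). Trophoblast genes were higher, with the transcription factor Tfap2c at 56.7 against 9.64 CPM and Hand1, a giant cell factor, at 50.9 against 1.39 CPM (adjusted p 0.743 after partner RNA was subtracted), in the stem cell list (9 of 15 rose and 0 fell, 10 and 0 adjusted over the list alone, median log2 2.12, adjusted p = 1.95e-07, 0.525 after partner RNA was subtracted). They moved with a TS share of 6.25 ± 3.13%, beside a PrES share of 0.1 ± 0.12%. The subtracted share was estimated from the excess of TS-specific genes, so the calls lost after subtraction do not settle the source. Imprinted genes had a median and a mean of opposite sign (3 of 19 rose and 6 fell, 3 and 7 adjusted over the list alone, median log2 -0.37, mean log2 0.03, tested direction down, adjusted p = 0.0389, 0.0805 with an estimated correlation). The test called 1111 genes higher and 781 lower of 15219, with 277 partner genes among the rises. The count of 1892 was 996 and 1155 without replicates 1 and 2 of ES alone, 1194 and 1062 without replicates 1 and 2 of ES with TS+PrES.

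With TS+XEN cells, naive genes were higher, and core genes were lower only before subtraction. Zfp42 rose 3.05-fold (log2 1.61 ± 0.11, 456 ± 10.8 against 149.5 ± 8.48 CPM, adjusted p = 8.15e-11) in a higher list (12 of 14 rose and 0 fell, median log2 1.76, adjusted p = 1.49e-19). Pou5f1 fell 1.67-fold (193 ± 6.39 against 322 ± 19.3 CPM, adjusted p 0.257 after partner RNA was subtracted) and Tdgf1 2.33-fold (646 ± 17.8 against 1500 ± 38.8 CPM) in the core list (2 of 14 rose and 9 fell, median log2 -0.41, adjusted p = 0.00011, 0.0717 with an estimated correlation, 0.996 after partner RNA was subtracted), and Nanog was at 216 against 202 CPM (adjusted p = 0.435), called higher after partner RNA was subtracted (6.07e-05). Formative genes were lower (1 of 14 rose and 7 fell, 1 and 10 adjusted over the list alone, median log2 -0.76, adjusted p = 8.14e-05), as were FGF-ERK targets (2 of 13 rose and 7 fell, 2 and 8 adjusted over the list alone, median log2 -0.63, adjusted p = 0.00226) such as Dusp6 (129.9 ± 3.42 against 281 ± 15.9 CPM). Hypoxia genes were higher (13 of 16 rose and 0 fell, median log2 0.76, adjusted p = 2.53e-16). In it, Bnip3 was at 226 ± 45.5 against 54.8 ± 4.13 CPM. The immediate early gene Fos, which marks handling stress, rose (32.3 against 6.43 CPM) in its list (5 of 13 rose and 1 fell, 6 and 1 adjusted over the list alone, median log2 0.66, adjusted p = 0.0124, 0.0799 with an estimated correlation, 0.799 after partner RNA was subtracted). Trophoblast and endoderm genes were higher, including Hand1 (287 against 1.39 CPM), Elf5 (26 CPM, no count alone, at least 131-fold, adjusted p 1 after subtraction and 0.314 by DESeq2) and Lama1 (129.6 against 3.13 CPM, log2 2.59 and adjusted p 0.081 after subtraction). They moved with a TS share of 20.32 ± 0.14% from 6 genes (13.79 and 13.86% from 14 genes at the 16-fold threshold, and 20.94 and 21.15% against 19.48 and 19.13% relative to TS cells of the same coculture, as subtracted) and a XEN share of 4.89 ± 0.37%. Subtracting that RNA ended the call of the trophoblast stem cell list (12 of 15 rose and 1 fell, 14 and 1 adjusted over the list alone, median log2 3.17, adjusted p = 1.46e-14, 0.668 after partner RNA was subtracted) and of the primitive endoderm list (15 of 19 rose and 0 fell, 17 and 0 adjusted over the list alone, median log2 3.31, adjusted p = 1.38e-23, 0.878 after partner RNA was subtracted). Of 15219 genes, 1473 rose and 1555 fell, with 779 partner genes among the rises. Without partner genes, 655 were higher and 1478 lower. The count of 3028 was 1740 and 1970 without replicates 1 and 2 of ES alone.

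**Figure D1:**
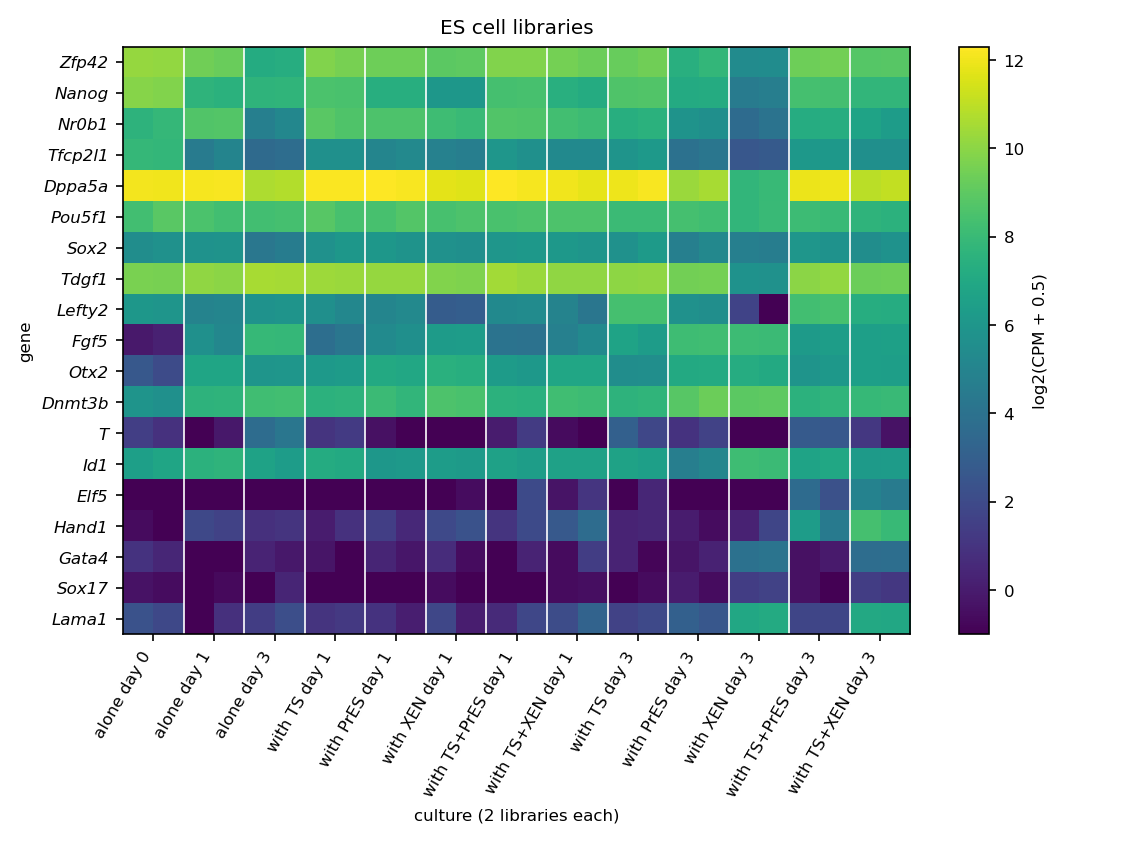
Levels of selected genes in the 26 ES cell libraries, as log2 of CPM plus 0.5, with 2 libraries per culture in adjacent columns. At day 3 the naive gene Zfp42 was brighter with TS cells than alone, and Nanog and Tdgf1 were darkest with XEN cells.

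With ES cells, TS cells had higher Eomes, Elf5 and cell cycle genes than alone. Eomes rose 39.7-fold against TS cells alone (log2 5.31 ± 0.27, 98.4 ± 0.47 against 2.49 ± 1.53 CPM, adjusted p = 2.91e-12) and Elf5 5.5-fold (212 ± 15.5 against 38.4 ± 3.4 CPM). Esrrb, an orphan receptor of TS and ES cells, rose 32.7-fold (51.3 ± 7.8 against 1.55 ± 0.0241 CPM), and Cdx2 was at 4.61 CPM with no count alone (at least 18.8-fold). FGF-ERK targets were higher (10 of 13 rose and 1 fell, 10 and 2 adjusted over the list alone, median log2 3.09, adjusted p = 1.72e-11), such as Dusp6 (102 ± 10.6 against 1.17 ± 0.761 CPM) and Spry4, a feedback inhibitor (45.2 against 0.569 CPM). Cell cycle genes were higher (18 of 19 rose and 0 fell, median log2 1.26, adjusted p = 7.35e-19). In it, Plk1 was at 163 against 36.4 CPM. BMP targets were higher (6 of 8 rose and 0 fell, median log2 2.41, adjusted p = 0.000127). In it, Id2 was at 513 against 61 CPM. Differentiated trophoblast genes were lower (1 of 17 rose and 12 fell, 1 and 13 adjusted over the list alone, median log2 -2.67, adjusted p = 2.04e-08), including Plac1 (19.8 ± 8.47 against 1099 ± 121 CPM) and Nrk (25.5 against 860.3 CPM). Interferon genes were lower (0 of 10 rose and 9 fell, median log2 -3.46, adjusted p = 2.39e-05). Stat1 was 4.96-fold lower. Cdkn1c, an imprinted cell cycle inhibitor of giant cells, fell 22.5-fold (30.2 ± 6.34 against 679 ± 50.6 CPM). The trophoblast stem cell list itself went both ways (8 of 15 rose and 7 fell, median log2 1.75, adjusted p = 0.0211). The test called 5880 of 14568 genes (3071 higher, 2809 lower). Genes at least 4-fold higher in ES cells made up 651 of the rises, and the ES share was 1.33 ± 0.07% (0.46% at the 64-fold threshold).

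With PrES cells, TS cells had higher Eomes, Elf5 and cell cycle genes. Eomes rose 15.3-fold (log2 3.94 ± 0.28, 37.8 ± 7.63 against 2.49 ± 1.53 CPM, adjusted p = 3.4e-09), Elf5 rose 2.08-fold (80.1 ± 8.78 against 38.4 ± 3.4 CPM) and Bmp4, a ligand of extraembryonic ectoderm, rose 7.89-fold (34.4 ± 8.38 against 4.40 ± 2.45 CPM). Cell cycle genes were higher (14 of 19 rose and 0 fell, 15 and 0 adjusted over the list alone, median log2 0.64, adjusted p = 4.55e-12), as were BMP targets (6 of 8, adjusted p = 6.27e-07), with Id2 at 327 ± 12.4 against 61 ± 14.4 CPM. FGF-ERK targets were higher (7 of 13 rose and 1 fell, median log2 1.62, adjusted p = 0.00204, 0.0605 with an estimated correlation). In it, Dusp6 was at 10.9 against 1.17 CPM. Differentiated trophoblast genes were lower (1 of 17 rose and 10 fell, 1 and 11 adjusted over the list alone, median log2 -1.23, adjusted p = 5.62e-05). In it, Nrk was at 238 against 860.3 CPM and Plac1 at 315 against 1099 CPM. Interferon genes were lower (0 of 10 rose and 6 fell, 0 and 7 adjusted over the list alone, median log2 -1.31, adjusted p = 5.3e-05). Ctsj, a placental cathepsin gene, had no count, from 57.8 CPM alone (at least 226-fold lower). Hand1 rose (1075 against 611 CPM). Of 14568 genes, 1740 rose and 1805 fell, 195 of the rises were partner genes, and the PrES share was 0.31 ± 0.0% (0.67% at the 16-fold and 0.03% at the 64-fold threshold). The count of 3545 was 2315 without replicate 1 of TS alone, 2258 without replicate 2 of TS with PrES.

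With XEN cells, TS cells had higher cell cycle and BMP target genes. Eomes rose 11.5-fold (log2 3.52 ± 0.28, 28.4 ± 2.97 against 2.49 ± 1.53 CPM, adjusted p = 3.05e-08), Dusp6 rose 17.8-fold (20.7 ± 2.23 against 1.17 ± 0.761 CPM), and Elf5 was at 48.8 against 38.4 CPM (adjusted p = 0.0542). Elf5 was called higher with the replicate block (0.0384), with the block without the run of 5 deeper libraries (0.0381), after subtraction (0.0475) and without replicate 1 of TS with XEN (0.0266). Cell cycle genes were higher (17 of 19 rose and 0 fell, 18 and 0 adjusted over the list alone, median log2 0.88, adjusted p = 3.19e-29), including the anaphase activator Cdc20 (2.68-fold). BMP targets were higher (4 of 8 rose and 1 fell, median log2 1.78, adjusted p = 2.09e-05). In it, Id3 was at 212 against 50.4 CPM. Cholesterol genes were higher (10 of 18 rose and 0 fell, 12 and 0 adjusted over the list alone, median log2 0.50, adjusted p = 2.02e-08). It included the mevalonate enzyme Mvd at 106 against 43.9 CPM. Interferon genes were lower (0 of 10 rose and 9 fell, median log2 -2.68, adjusted p = 1.49e-09). In it, Irf7, a master regulator, was at 4.78 against 35.0 CPM. Differentiated trophoblast genes were lower as a list (2 of 17 rose and 9 fell, median log2 -0.94, adjusted p = 0.0129), but Hand1 rose (1744 ± 30.4 against 611 ± 113 CPM). Core pluripotency genes had a median and a mean of opposite sign (6 of 13 rose and 1 fell, median log2 0.23, mean log2 -0.05, tested direction up, adjusted p = 0.000346). Primitive endoderm genes were higher (7 of 17 rose and 1 fell, 8 and 1 adjusted over the list alone, median log2 0.88, adjusted p = 0.00679, 0.503 after partner RNA was subtracted). In it, Lama1 was at 17.6 against 1.55 CPM and a XEN share of 0.58 ± 0.1% (0.36% at the 16-fold threshold, Lama1 adjusted p 0.989 after subtraction). The test called 1616 genes higher and 948 lower of 14568, with 155 partner genes among the rises. A model on the compared groups alone gave 1589 and 1416. The count of 2564 was 1662 and 1621 without replicates 1 and 2 of TS alone, 1559 and 1589 without replicates 1 and 2 of TS with XEN.

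In the 3-way culture with ES and PrES cells, Eomes rose 42.2-fold in TS cells (log2 5.40 ± 0.27, 105 ± 6.86 against 2.49 ± 1.53 CPM, adjusted p = 1.62e-12), Elf5 5.78-fold (221 ± 11.1 against 38.4 ± 3.4 CPM) and Bmp4 52.3-fold (228 ± 4.74 against 4.40 ± 2.45 CPM). FGF-ERK targets were higher (9 of 13 rose and 0 fell, median log2 2.99, adjusted p = 8.03e-12). In it, Dusp6 was at 131 against 1.17 CPM. Cell cycle genes were higher (18 of 19 rose and 0 fell, median log2 1.54, adjusted p = 2.49e-22). In that list was the ribonucleotide reductase gene Rrm2 at 1047 against 312 CPM. Differentiated trophoblast genes were lower (1 of 17 rose and 13 fell, 1 and 15 adjusted over the list alone, median log2 -3.25, adjusted p = 1.8e-08). In it, Plac1 was at 29.6 against 1099 CPM. Interferon genes were lower (0 of 10 rose and 9 fell, median log2 -4.30, adjusted p = 7.5e-05). In it, Usp18, a feedback protease, was at 1.69 against 49.5 CPM. Of 14568 genes, 6262 changed (3235 higher, 3027 lower). The ES share was 0.82 ± 0.22%, and 822 of the rises were genes at least 4-fold higher in a partner. Such a gene can also be one that TS cells lost alone: Nr0b1 was at 149.9 CPM with no count alone at day 3 (at least 612-fold), and at 170 CPM in TS cells alone at day 0.

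With ES and XEN cells together, TS cells had Eomes 39.1-fold higher (log2 5.29 ± 0.27, 96.7 ± 3.14 against 2.49 ± 1.53 CPM, adjusted p = 2.52e-12) and Elf5 6.23-fold higher (239 ± 11.7 against 38.4 ± 3.4 CPM). Cholesterol synthesis genes were higher (17 of 18 rose and 1 fell, median log2 1.12, adjusted p = 8.01e-09). That list held the synthase Hmgcs1 at 406 ± 14.3 against 152 ± 0.864 CPM, beside the cell cycle (18 of 19 rose and 0 fell, median log2 1.61, adjusted p = 9.01e-24) and FGF-ERK (9 of 13 rose and 0 fell, 10 and 0 adjusted over the list alone, median log2 2.61, adjusted p = 7.51e-11) lists. The differentiated trophoblast list was lower (1 of 17 rose and 12 fell, 1 and 15 adjusted over the list alone, median log2 -2.67, adjusted p = 5.65e-07). In it, Nrk was at 52.4 against 860.3 CPM. The XEN transcripts Lama1 (22.4 against 1.55 CPM) and Rbp4 (22.7 against 0.426 CPM) were higher, with a XEN share of 0.83 ± 0.06% (0.13% at the 16-fold threshold) and an ES share of 0.4 ± 0.03% (Lama1 adjusted p 0.821 after subtraction). The test called 6474 of 14568 genes (3318 higher, 3156 lower), 893 of the rises being partner genes.

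**Figure D2:**
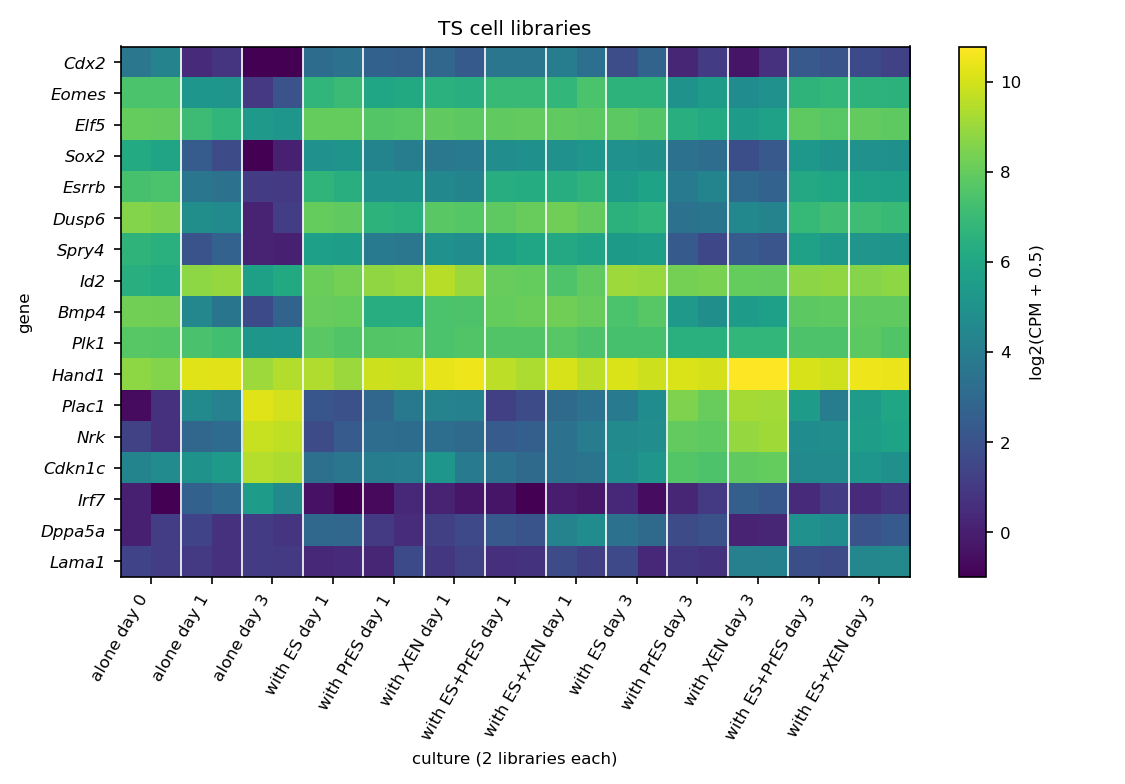
Levels of selected genes in the 26 TS cell libraries, as log2 of CPM plus 0.5, with 2 libraries per culture in adjacent columns. At day 3 Eomes, Elf5 and Dusp6 were darkest alone and brightest with ES cells in 2-way or 3-way cultures, and Plac1 and Nrk ran the other way.

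With ES cells, PrES cells had higher FGF-ERK targets and lower parietal endoderm genes. Fgf5 rose 12-fold (log2 3.59 ± 0.34, 83.5 ± 12.6 against 6.93 ± 0.0588 CPM, adjusted p = 1.89e-06). Dusp6 rose 12.3-fold (35.5 ± 2.57 against 2.86 ± 0.101 CPM) and Etv5, an ETS factor, 13.5-fold (46.3 ± 1.36 against 3.37 ± 0.826 CPM), within the FGF-ERK list (7 of 13 rose and 0 fell, 8 and 0 adjusted over the list alone, median log2 1.11, adjusted p = 3.97e-12). After ES RNA was subtracted the list still passed (adjusted p = 0.00899) and so did Etv5, but Dusp6 turned lower (0.00543), so its rise is not separable from ES RNA. Sparc fell 1.74-fold (6125 ± 113 against 10640 ± 488 CPM) in a lower parietal endoderm list (0 of 13 rose and 8 fell, 0 and 10 adjusted over the list alone, median log2 -0.65, adjusted p = 2.36e-09). Stress genes were lower (0 of 13 rose and 6 fell, median log2 -0.44, adjusted p = 6.62e-07). It included the stress factor Ddit3 at 46.6 against 119.9 CPM. Spink1, a trypsin inhibitor of visceral endoderm, rose 4-fold (219 ± 11.2 against 54.8 ± 5.8 CPM), as did Car4, a carbonic anhydrase (166 ± 7.22 against 43.9 ± 1.73 CPM). The visceral list was higher (3 of 15 rose and 0 fell, median log2 0.85, adjusted p = 0.00138). Id1 fell (18.1 ± 2.23 against 54.2 ± 10.1 CPM). Formative (8 of 12 rose and 0 fell, 11 and 0 adjusted over the list alone, median log2 2.06, adjusted p = 1.2e-17), core pluripotency (7 of 14 rose and 0 fell, 11 and 0 adjusted over the list alone, median log2 0.69, adjusted p = 2.47e-13, 0.44 after partner RNA was subtracted) and imprinted genes (8 of 18 rose and 1 fell, 8 and 2 adjusted over the list alone, median log2 0.76, adjusted p = 4.56e-05, 0.183 after partner RNA was subtracted) were higher, with Utf1 at 245 against 76.8 CPM, while the ES share was 10.48 ± 0.59%. Nanog was at 54.2 against 44.3 CPM (adjusted p = 0.542) and Gata4 at 115 against 159 CPM (adjusted p = 0.12). Gata4 was called lower with the replicate block (0.0296), with the block without the run of 5 deeper libraries (0.0079), on the compared groups (0.046) and without the filter (0.0368). Of 14626 genes, 684 rose and 543 fell, and 374 of the rises were partner genes. Without those, 261 were higher and 470 lower, and 407 genes were called after ES RNA was subtracted. The count of 1227 was 502 and 544 without replicates 1 and 2 of PrES alone, 556 and 523 without replicates 1 and 2 of PrES with ES.

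With TS cells, PrES cells changed in few genes. Ttr fell 2.85-fold (log2 -1.51 ± 0.17, 27.3 ± 0.622 against 77.8 ± 8.73 CPM, adjusted p = 0.000109) in a visceral endoderm list that was lower (0 of 15 rose and 3 fell, 0 and 5 adjusted over the list alone, median log2 -1.51, -0.67 with members at 0 set to their bound, adjusted p = 1.03e-08). Serping1, a complement inhibitor, rose 2.85-fold (65.3 ± 4.18 against 22.9 ± 1.36 CPM, adjusted p = 0.000109). Ldha rose 1.78-fold (789 ± 62.2 against 443 ± 10.9 CPM), and the hypoxia list was higher (3 of 17 rose and 0 fell, 9 and 0 adjusted over the list alone, median log2 0.57, adjusted p = 1.89e-10), as was the immediate early list (3 of 13 rose and 1 fell, median log2 0.82, adjusted p = 4.01e-07). The list of fibroblast markers was higher too (0 of 14 rose and 0 fell, 2 and 0 adjusted over the list alone, median log2 0.54, adjusted p = 0.00944, 0.151 with an estimated correlation), with member sums of 53.1 and 106.2 CPM per library against 53.3 and 29.2 alone. Gata4 was at 165 against 159 CPM (adjusted p = 0.968) and Pdgfra, a receptor of primitive endoderm, at 159 against 139 CPM (adjusted p = 0.689). The test called 104 of 14626 genes (46 higher, 58 lower), 160 by DESeq2 and 292 (162 higher, 130 lower) without the filter. Without partner genes there were 22 higher and 46 lower, and the TS share was 1.32 ± 0.08%. The count was 25 and 30 without replicates 1 and 2 of PrES alone, 28 and 26 without replicates 1 and 2 of PrES with TS.

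In the 3-way culture with ES and TS cells, PrES cells had higher glycolytic genes and lower primitive endoderm genes. Ldha rose 3.32-fold (log2 1.73 ± 0.10, 1474 ± 41.5 against 443 ± 10.9 CPM, adjusted p = 6.94e-09) and Slc2a1 4.23-fold (253 ± 60.6 against 59.9 ± 0.899 CPM), within the hypoxia list (11 of 17 rose and 0 fell, median log2 0.90, adjusted p = 3.22e-14). Gata6 fell 2.28-fold (64.4 ± 12.6 against 146 ± 24.9 CPM) and Foxa2, an endoderm forkhead factor, fell (23.2 against 67.3 CPM), and the primitive endoderm list was lower (0 of 19 rose and 12 fell, median log2 -0.56, adjusted p = 8.32e-08). The tissue protease Plat fell (104 against 273 CPM) in a lower parietal list (1 of 13 rose and 8 fell, 1 and 9 adjusted over the list alone, median log2 -0.67, adjusted p = 5.2e-06). FGF-ERK targets were higher (9 of 13 rose and 0 fell, 10 and 1 adjusted over the list alone, median log2 1.26, adjusted p = 1.99e-10). In it, Etv5 was at 50.2 against 3.37 CPM. Id1 rose (118 ± 33.6 against 54.2 ± 10.1 CPM). Core pluripotency genes (11 of 14 rose and 0 fell, median log2 1.12, adjusted p = 4.64e-14) and NODAL targets (4 of 8 rose and 0 fell, median log2 0.94, adjusted p = 1.21e-07, 0.306 after partner RNA was subtracted) were higher, beside an ES share of 16.07 ± 9.64% and a TS share of 4.26 ± 1.52%. The test called 1155 genes higher and 1151 lower of 14626, 605 of the rises being partner genes. Without those the split was 506 and 1039, and 810 genes were called after partner RNA was subtracted. The count of 2306 was 1298 and 1106 without replicates 1 and 2 of PrES alone, 987 without replicate 1 of PrES with ES+TS.

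With ES cells, XEN cells raised a few visceral endoderm genes. Rbp4 rose 2.83-fold (1878 ± 184 against 665 ± 30.1 CPM, adjusted p = 1.18e-06), Spink1 rose 2.3-fold (277 ± 57.9 against 121 ± 28.6 CPM), and Lrp2 rose 1.52-fold (105 ± 7.7 against 69.2 ± 8.46 CPM), in a list with 3 of 12 members called higher (adjusted p = 6.77e-08). Leaving out 1 library ended 2 of these calls: Lrp2 (adjusted p 0.4 and 0.1 without replicates 1 and 2 of XEN alone, 0.45 without replicate 2 of XEN with ES) and Spink1 (0.202 without replicate 1 of XEN alone, 0.125 without replicate 2 of XEN with ES). FGF-ERK targets were higher as a list (0 of 13 rose and 0 fell, 3 and 0 adjusted over the list alone, median log2 0.21, adjusted p = 0.00531). Gata4 was at 323 against 320.1 CPM (adjusted p = 0.991), and the ES share was 0.32 ± 0.06%. The test called 35 of 14399 genes (21 higher, 14 lower), 96 by DESeq2, 242 without the filter (171 higher, 71 lower) and 81 with the replicate block. A model on the compared groups alone called 103 higher and 39 lower. The count was 2 and 5 without replicates 1 and 2 of XEN alone, 87 and 3 without replicates 1 and 2 of XEN with ES.

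With TS cells, XEN cells had higher hypoxia genes and Sox7. Sox7, a SOX factor of primitive endoderm, rose 1.84-fold (log2 0.88 ± 0.12, 246 ± 6.42 against 133 ± 15.4 CPM, adjusted p = 0.000481), and Ldha rose 1.6-fold (704 ± 80 against 438 ± 1.78 CPM) in the hypoxia list (7 of 17 rose and 0 fell, 9 and 0 adjusted over the list alone, median log2 0.35, adjusted p = 4.01e-10). Dusp6 rose 2.99-fold (21.1 ± 2.88 against 7.04 ± 0.0383 CPM) and Socs3 3.25-fold (31.8 ± 6.7 against 9.80 ± 0.0211 CPM), the latter in a higher immediate early and dissociation list (2 of 14 rose and 0 fell, 6 and 0 adjusted over the list alone, median log2 0.41, adjusted p = 8.19e-06), while S100a11, a calcium-binding protein, fell (79.1 ± 0.0356 against 143 ± 10.3 CPM). Gata6 was at 99.9 against 142 CPM (adjusted p = 0.119), and was called lower without the filter (0.00963), by DESeq2 (0.0495) and on the compared groups (0.0436). Differentiated trophoblast genes were higher (4 of 9 rose and 0 fell, 5 and 1 adjusted over the list alone, median log2 1.23, adjusted p = 5.47e-07, 0.109 after partner RNA was subtracted) at a TS share of 0.82 ± 0.28%. The test called 147 of 14399 genes (107 higher, 40 lower), and 344 by DESeq2, 429 without the filter and 355 in a model on the compared groups. The count was 58 and 34 without replicates 1 and 2 of XEN alone, 43 and 95 without replicates 1 and 2 of XEN with TS.

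In the 3-way culture, XEN cells had higher glycolytic genes. Ldha rose 2.83-fold (1240 ± 78.4 against 438 ± 1.78 CPM, adjusted p = 4.71e-09) in a higher hypoxia list (12 of 17 rose and 0 fell, 14 and 1 adjusted over the list alone, median log2 0.82, adjusted p = 1.42e-23). Frzb, a secreted WNT antagonist, rose 8.11-fold (127 ± 0.913 against 15.5 ± 2.11 CPM), and Cubn rose 3.61-fold (99.6 ± 5.54 against 27.6 ± 4.45 CPM). Sox7 rose (337 against 133 CPM) and Id3 rose 4.79-fold (72.2 ± 17.6 against 14.9 ± 2.41 CPM), whereas Mybpc3, a myosin-binding protein gene, fell (25.3 ± 8.17 against 119 ± 7.41 CPM). Cell cycle genes were higher (11 of 19 rose and 0 fell, 13 and 0 adjusted over the list alone, median log2 0.48, adjusted p = 1.51e-07, 0.0718 with an estimated correlation), as were amino acid stress genes (6 of 13 rose and 2 fell, 8 and 2 adjusted over the list alone, median log2 0.50, adjusted p = 8.62e-05, 0.109 with an estimated correlation). In it, Asns was at 213 against 71.8 CPM. Of 14399 genes, 1025 rose and 747 fell, 153 of the rises being partner genes. The ES share was 0.73 ± 0.37% and the TS share 1.56 ± 0.06%. The count of 1772 was 1110 and 721 without replicates 1 and 2 of XEN alone, 984 without replicate 2 of XEN with ES+TS, and 1102 in a model on the compared groups.

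**Figure D3:**
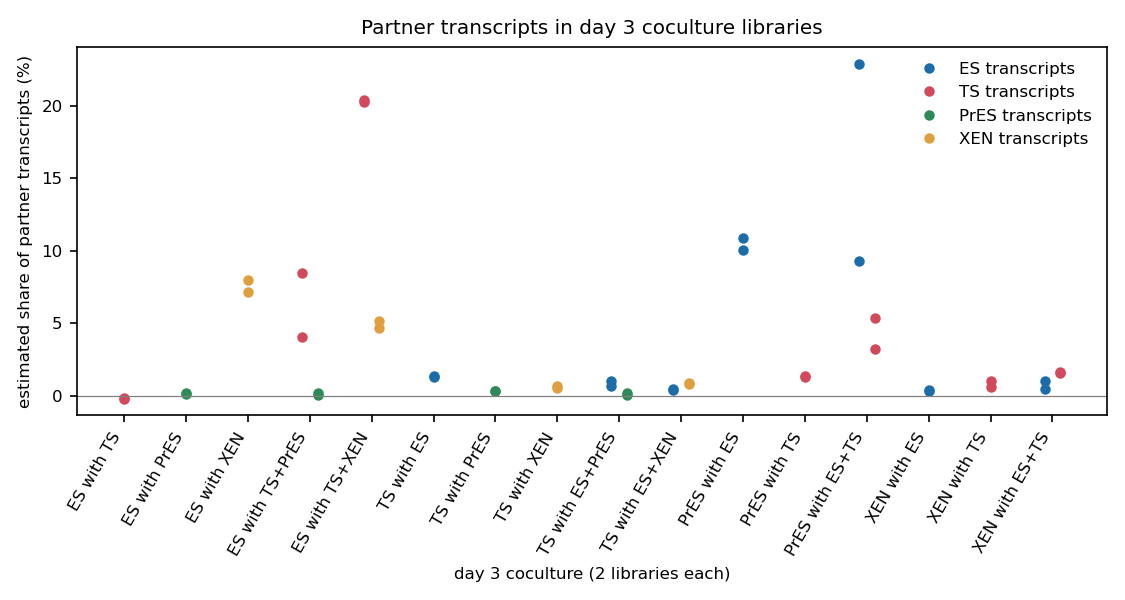
Estimated share of partner transcripts in each day 3 coculture library, in percent, with 1 point per library and partner. Shares above 4% were seen in ES with XEN, ES with TS+PrES, ES with TS+XEN, PrES with ES and PrES with ES+TS.

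The partner comparison placed ES cells with PrES cells against ES cells with XEN cells. Tdgf1 was 13.5-fold higher with PrES cells (log2 3.76 ± 0.07, 728 ± 24.8 against 53.9 ± 0.858 CPM, adjusted p = 1.2e-21), Nanog 5.94-fold (144 ± 5.01 against 24.2 ± 1.67 CPM) and Lefty1 10.1-fold (52.2 ± 2.72 against 5.18 ± 5.11 CPM). The XEN genes Gkn2, a secreted gastrokine, and Pga5 were lower (0 against 41.8 CPM, at least 160-fold, and 3.40 against 924 CPM). Pou5f1 was at 313 against 240 CPM (adjusted p = 0.15, 0.00189 without the low-count filter). The test called 962 genes (535 higher with PrES, 427 lower), 315 and 444 in a model on the compared groups. After partner RNA was subtracted, 416 were higher and 123 lower. The count was 576 without replicate 2 of ES with PrES, 534 and 555 without replicates 1 and 2 of ES with XEN. In 3-way cultures with TS cells, Nanog was 1.52-fold higher (329 ± 12.2 against 216 ± 4.89 CPM, adjusted p = 1.77e-05) with PrES than with XEN cells, with an adjusted p of 0.0832 after subtraction. There the test called 1667 genes (1039 higher, 628 lower), 530 and 510 in a model on the compared groups, and 607 and 216 after subtraction. The count was 638 without replicate 2 of ES with TS+PrES, 750 without replicate 1 of ES with TS+XEN.

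TS cells with PrES cells had Elf5 1.64-fold higher than with XEN cells (log2 0.71 ± 0.12, 80.1 ± 8.78 against 48.8 ± 6.28 CPM, adjusted p = 0.000605). Eomes was at 37.8 against 28.4 CPM (adjusted p = 0.195). The test called 1671 genes (516 higher with PrES, 1155 lower), 1079 and 1285 in a model on the compared groups, and 695 and 996 without the filter. The count was 1092 and 399 without replicates 1 and 2 of TS with PrES, 694 and 734 without replicates 1 and 2 of TS with XEN. In 3-way cultures with ES cells, 21 genes differed (8 higher with PrES, 13 lower), 51 by DESeq2 and 80 without the filter. They included the XEN gene Lama1 (2.9 against 22.4 CPM, adjusted p = 0.00122, 0.999 after subtraction, 0.0732 and 0.101 without replicates 1 and 2 of TS with ES+PrES), and Elf5 was at 221 against 239 CPM (adjusted p = 0.971). The count was 2 and 3 without replicates 1 and 2 of TS with ES+PrES, 10 and 4 without replicates 1 and 2 of TS with ES+XEN.

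Changes in 3-way cultures departed from the sum of the 2-way changes. In ES with TS and XEN cells, Tdgf1 exceeded the sum by log2 4.08 (adjusted p = 8.5e-20), Nanog by 2.13 (adjusted p = 2.68e-11) and Dppa5a by 1.81 (adjusted p = 1.86e-09), so these genes were not as low as the XEN change predicted. The test called 855 genes (531 above the sum, 324 below), and 536 and 531 without the filter. The count was 454 without replicate 1 of ES alone, 486 without replicate 2 of ES with TS, 510 and 546 without replicates 1 and 2 of ES with XEN. In ES with TS and PrES cells, Tdgf1 was above the sum by 1.06 (adjusted p = 9.94e-08) among 647 genes (321 above, 326 below). Without the filter the split was 311 above and 590 below, and 393 genes were called after subtraction. The TS share in ES with TS+PrES was 6.25%. The count was 321 without replicate 1 of ES alone, 392 without replicate 2 of ES with PrES, 338 without replicate 2 of ES with TS, 407 without replicate 2 of ES with TS+PrES.

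In TS cells, Eomes lay below the sum with ES and PrES cells (log2 -3.85, adjusted p = 3.82e-07), as each partner alone had raised it and the 3-way level stayed near that with ES cells. The test called 1852 genes (907 above, 945 below), 1218 without replicate 1 of TS alone, 1177 without replicate 2 of TS with PrES. With ES and XEN cells, Eomes (log2 -3.55, adjusted p = 2.07e-06) and Dusp6 (log2 -3.79, adjusted p = 3.22e-07) lay below the sum, and Trp53, the tumour suppressor p53, did too (log2 -1.52, adjusted p = 2.86e-07). There were 1152 such genes (438 above, 714 below), 758 without replicate 1 of TS alone, 680 without replicate 1 of TS with ES, 701 without replicate 2 of TS with ES+XEN, 712 without replicate 1 of TS with XEN.

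In PrES cells, Id1 (log2 2.44, adjusted p = 0.00203) was above the sum among 23 genes (7 above, 16 below), 89 by DESeq2 and 245 without the filter. Subtraction left 11 above and 9 below, the block without the run of 5 deeper libraries gave 13 and 19, and the count was 4 and 2 without replicates 1 and 2 of PrES alone, 4 and 11 without replicates 1 and 2 of PrES with ES, 13 without replicate 1 of PrES with ES+TS, 1 and 12 without replicates 1 and 2 of PrES with TS. In XEN cells Id3 was above the sum (log2 3.35, adjusted p = 1.26e-05) and Id1 too (log2 1.58, adjusted p = 0.00384). There were 18 genes (9 above, 9 below), 5 above and 0 below with RLE size factors, 59 by DESeq2 and 182 without the filter (61 and 121). Subtraction left 6 above and 0 below, and the count was 2 and 5 without replicates 1 and 2 of XEN alone, 43 and 4 without replicates 1 and 2 of XEN with ES, 6 without replicate 1 of XEN with ES+TS, 4 and 4 without replicates 1 and 2 of XEN with TS.

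At day 1, Nanog differed most clearly between ES cocultures and ES cells alone (adjusted p = 7.07e-15). It stood at 189.6 CPM alone, 366 with TS, 162 with PrES, 66.4 with XEN, 341 with TS+PrES and 159 with TS+XEN. The joint test called 813 of 15219 genes, and 1567 without the low-count filter. In TS cells, Dusp6 (adjusted p = 2.55e-11) was at 26.4 CPM alone, 248 with ES, 93.9 with PrES and 209.8 with XEN. Eomes (adjusted p = 1.2e-06) was at 35.5 CPM alone and 121 with ES. The joint test called 3933 of 14568 genes.

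In XEN cells at day 1, the pluripotency transcripts Utf1 (adjusted p = 8.77e-08), Dppa5a (adjusted p = 1.01e-07) and Tdgf1 (adjusted p = 2.49e-06) had the smallest p-values, and 0.371, 0.146 and 0.974 after partner RNA was subtracted. Dppa5a was at 0.0619 CPM alone, 4.23 with ES and 73.6 with ES+TS, beside an ES share of 0.01 ± 0.06% and 1.82 ± 0.12%. The joint test called 540 of 14399 genes, 1251 without the filter. The count was 132 and 100 without replicates 1 and 2 of XEN alone, 187 and 130 without replicates 1 and 2 of XEN with ES+TS. In PrES cells the joint test called 6333 of 14626 genes, led by Srm, a spermidine synthase (adjusted p = 9.31e-14), Timp1, a protease inhibitor (adjusted p = 4.54e-13), and Gje1, a connexin (adjusted p = 4.71e-13). The day 1 cells alone were all in the run of 5 deeper libraries and the cocultures in the other runs, so these values cannot be assigned to culture or run. Fibroblast markers differed as well, with sums of 522.1 and 378.6 CPM in PrES cells alone at day 1, 15.1 to 56.6 in the cocultures, and 45.5 and 50.4 in the day 0 libraries of the same run.

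Across lists, 186 results passed in the 16 coculture and 67 in the 6 monoculture comparisons. With an estimated correlation, 94 of these 253 no longer passed, leaving 129 and 30. The X inactivation and Y-linked list passed in none (smallest adjusted p 0.204, XEN with TS). It pools Xist with Y-linked genes, so opposite changes can cancel. In ES with TS+XEN at day 3 (largest TS share), Xist was at 19.5 and 35.8 CPM against 2.6 and 6.7 alone. The immediate early and dissociation list was also higher in ES with XEN (adjusted p = 0.0185) and over 3 days alone in TS (0.00486), PrES (0.0257) and XEN cells (0.000929), and lower in TS with ES+XEN (0.0277) and in PrES against XEN cells at day 3 (0.0249). None of these 6 passed with an estimated correlation (0.0739 to 0.282).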

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

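The subtraction of partner RNA, at any share, and the tests of XEN RNA in ES libraries and of ES RNA in PrES libraries were chosen after those results were seen, and the tests of the day 1 PrES difference before.

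Coculture effects at day 3 differed from those at day 1, by an edgeR test of the interaction, in 750 genes for ES with TS, 331 with PrES, 673 with XEN, 672 with TS+PrES and 1195 with TS+XEN. In TS cells the numbers were 3067 with ES, 2652 with PrES, 1338 with XEN, 3376 with ES+PrES and 3641 with ES+XEN. For TS with XEN, 1 of the 2 day 1 libraries came from the run of 5 deeper libraries, and that pair differed by a chi-square of 51.84 per degree of freedom, against 2.74 to 9.6 in the other TS groups. In XEN cells they were 7 with ES, 2 with TS and 87 with ES+TS. In PrES cells they were 4206 with ES, 4092 with TS and 3973 with ES+TS, where the day 1 cells alone came from another run and held more fibroblast marker transcripts. The day 3 response of PrES cells differed from that of XEN cells in 284 genes with ES (133 higher in PrES, 151 lower), among them Car4, a carbonic anhydrase (log2 difference 1.65 ± 0.17, adjusted p = 1.79e-06). It differed in 51 genes with TS (8 and 43) and 1020 with ES+TS (252 and 768). The ES share was 10.48% in PrES with ES and 0.32% in XEN with ES, and 16.07% and 0.73% in the 3-way cultures. After partner RNA was subtracted, 98 genes differed with ES (40 and 58), 45 with TS (8 and 37) and 581 with ES+TS (148 and 433). Subtraction removed TS RNA too, and the cause of the drop was not tested.

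Endoderm genes were higher in ES cells cultured with XEN cells. If XEN RNA were the source, each gene should reach the fraction of its XEN level that XEN-specific genes reach. The 20 called endoderm genes had a median of 5.65% (1.81 to 10.1), 5 below and 0 above the band of 39 XEN-specific genes. It ran from 4.56 to 12.4 (10th to 90th percentile, median 7.56). XEN RNA, carried-over or free, is a possible source, as is an ES endoderm programme that raised the 39 too. With XEN RNA subtracted at the 10th percentile, 3 of the 20 were still called higher by edgeR (Foxa2, Lama1 and Srgn), beside 18 of the 39 XEN-specific genes, and 0 of the 20 at the median, at the 90th percentile and at the estimated share. Those shares exceed the median of the 20, so little is left by construction, and both stay open.

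Formative epiblast genes were higher in PrES cells cultured with ES cells. Other than Fgf5, 7 such genes stood at a median of 23.2% of their ES level (quartiles 15.3 to 33.8), and 28 ES-specific genes ran from 9.21 to 17.6, with 4 of the 7 above that band and 3 inside it. After subtraction the whole list still passed (adjusted p = 2.8e-07), unlike core pluripotency (0.44) and imprinted genes (0.183), and Dnmt3b, Etv4, Fgf5 and Otx2 stayed called. The 11 members other than Fgf5 gave p = 4.6e-06 at the estimated shares (13.12 and 12.91% of ES with PrES, 0.00376 with an estimated correlation), and 4.47e-06, 0.0727 and 0.87 with the share set at 13, 17.6 and 25%, where 3, 3 and 1 of them were called higher. This argues against ES RNA at the estimated share as the whole source, but the list depends on the share within the band, so the explanation stays open for genes other than Fgf5. Fgf5 at day 1 was at 37.7% of its ES level in the lower library (58.9 in the other) and the highest ES-specific gene at 21.2, against PrES alone (0.794 CPM) from another run, so ES RNA alone is unlikely to explain Fgf5.

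The day 1 difference between PrES cells in coculture and alone may come from the run, as read from the sample codes. In TS with XEN at day 1, the 1 pair of replicates split between the same runs differed along the same genes (r = 0.618 over 7385 genes), against -0.389 to 0.0479 in the other 12 TS pairs. A response to the partner is also seen where no run differs, as 534 genes differed between PrES with ES and PrES with TS at day 1 (272 higher, 262 lower), among them Cyp26a1, a retinoic acid hydroxylase, and Lefty2. Run and partner may therefore both contribute. The fibroblast marker sums given above go with the comparison and not with the run. Their contribution was not tested, and the shares of all of these stay open.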

How the results depend on the processing

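Subtraction and the 16-fold and 64-fold thresholds were chosen after the results were seen, and the others before. Of 428 counts recomputed under an alternative, 307 stayed within 1.5 times the reported count and 121 moved further. Of 1198 list results, 1045 kept their direction and side of the threshold, 150 no longer passed and 3 reversed. Of 44 shares, 26 moved by less than 1 SD and 18 by more, among them TS in ES with TS+XEN (20.32 to 13.79 and 13.86% at 16-fold), ES in TS with ES (1.33 to 0.46% at 64-fold), XEN in TS with ES+XEN (0.83 to 0.13% at 16-fold) and PrES in TS with PrES (0.31 to 0.67% at 16-fold and 0.03% at 64-fold). Genes near 10 counts per library limit what these depths resolve. The simulated 28 to 55% for 2-fold changes holds for 200 changed genes only. Where a library is left out, the lone sample of its group is assumed to vary like the other groups.

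DESeq2 moved the counts of PrES with TS from 104 to 160, XEN with ES from 35 to 96, XEN with TS from 147 to 344, the PrES against XEN partner comparison in 3-way TS cultures from 21 to 51, and non-additivity from 23 to 89 in PrES and from 18 to 59 in XEN cells. RLE size factors moved the last to 5. With no low-count filter, the counts were 292 for PrES with TS, 242 for XEN with ES, 429 for XEN with TS, 1567 for ES at day 1, 1251 for XEN at day 1, 80 for the partner comparison in 3-way TS cultures, and 245 and 182 for non-additivity in PrES and XEN cells, with more genes tested. A model on the compared groups alone, with fewer samples, gave 205 for PrES with TS, 142 for XEN with ES, 355 for XEN with TS, 1102 for XEN with ES+TS, 1040 for the partner comparison in 3-way ES cultures and 39 in 3-way TS cultures. Subtracting partner RNA gave 407 for PrES with ES, 810 for PrES with ES+TS, 539 for the partner comparison in ES cells, 823 in 3-way ES and 11 in 3-way TS cultures, and 393 for non-additivity in ES with TS+PrES and 6 in XEN cells. The difference between the PrES and XEN responses went from 284 to 98 genes with ES and from 1020 to 581 with ES+TS. Subtraction reversed the parietal endoderm list in ES with XEN (adjusted p = 5.57e-14, lower) and in ES with TS+XEN (0.000213, lower), and the primitive endoderm list in ES with XEN (9.35e-07, lower). Log2 changes turned to -7.28 for Lama1, -12.98 for Sparc and -4.92 for Gata4 in ES with XEN, -1.08 for Hand1 in ES with TS+PrES and -7.67 for Dusp6 in PrES with ES, fitted on counts near 0 after subtraction. Leaving out partner genes, with fewer genes tested, gave 731 for PrES with ES and 68 for PrES with TS. For DESeq2, RLE size factors and subtraction, the cause was not tested.

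Replicate numbers mostly followed the run codes, and the samples were not treated as pairs. The median correlation of replicate differences between groups was 0.024 in ES, 0.019 in TS, 0.073 in PrES and 0.048 in XEN cells, but 8 of 78, 16 of 78, 16 of 36 and 13 of 36 group pairs lay above 0.1, up to 0.374, so some shared replicate effect is not excluded. A replicate block moved XEN with ES from 35 to 81, and the block without the third run code moved the partner comparison in 3-way TS cultures from 21 to 35. The cause was not tested. Fry gave 117 passing monoculture lists and subtraction 154 coculture lists.

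Leaving out 1 library, with fewer samples, gave 898 to 1392 for ES with TS, 302 to 560 with PrES, 986 to 1136 with XEN, 996 to 1194 with TS+PrES and 1740 to 2040 with TS+XEN. It gave 2258 to 2698 for TS with PrES and 1559 to 1662 with XEN, 502 to 556 for PrES with ES, 25 to 30 with TS and 987 to 1790 with ES+TS, and 2 to 87 for XEN with ES, 34 to 95 with TS and 721 to 1566 with ES+TS. The day 1 test in XEN cells gave 100 to 618. The partner comparison gave 534 to 706 in ES, 399 to 1092 in TS, 638 to 1170 in 3-way ES and 2 to 10 in 3-way TS cultures. Non-additivity gave 321 to 520 for ES with TS+PrES, 454 to 686 with TS+XEN, 1177 to 1517 for TS with ES+PrES, 680 to 805 with ES+XEN, 1 to 30 in PrES and 2 to 43 in XEN cells.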

Other observations

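Park2 was not alone among genes that were higher in ES cocultures. It stood at 9.15 CPM in ES cells alone, 325 with TS, 189 with PrES and 59.0 with XEN. Cyp2e1, a cytochrome P450 gene, was at 3.01, 28.2, 21.8 and 7.26 CPM in the same groups, and the brain RNA gene Bc1 at 3.02, 32.3, 21.9 and 7.68.

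Day 1 pairs against the same cells alone gave, in ES cells, 161 genes with TS, 69 with PrES, 278 with XEN, 260 with TS+PrES and 420 with TS+XEN. TS cells gave 2636 with ES, 1829 with PrES and 3277 with XEN, where 1 library of the last came from the deeper run. XEN cells gave 8 with ES, 28 with TS and 1380 with ES+TS. Col1a1, a fibroblast collagen gene, was at 91.2 CPM in PrES cells alone at day 1, 8.05 at day 0 and 6.16 at day 3.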
